A study of Drosophila mojavensis with 172 samples.

How the data were processed

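RNA from whole Drosophila mojavensis, a cactus-breeding fly of the Sonoran Desert, was measured on 172 single-colour NimbleGen arrays, each with 1 value for each of 14528 transcripts. Per the labels' protocols, total RNA was extracted with a column kit, copied into double-stranded cDNA and labelled with Cy3. The authors deposited 1 table of log2 values made with RMA, per the submitters' processing notes. The version, the software and the arrays over which the RMA steps were run are not given in the sources used here. The deposited log2 values ran from 7.25 to 15.93. Array medians lay between 10.96 and 11.48, and the SD of the values on an array lay between 1.28 and 1.77, so the arrays do not share 1 distribution. No scanner files and no background measurements were used here. Slide and array position were not given in the labels, so no slide block was fitted.

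Groups came from the labels and were set before the data were examined. Each group is 1 population, 1 diet and 1 stage, which gives 54 groups of 1 to 5 arrays, 8 of them with 1 array. No pair of arrays held identical values. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. In 1 array of 14-day Las Bocas females on agria (replicate 1), 1 label gives an age of 10 days while the title, source and description give 14 days. It was kept at 14 days and left out as an alternative. The 2 arrays of 4-day females were in the fit for the spread and in no comparison.

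The main model was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the log2 values as deposited, with 1 mean for each group and 118 residual degrees of freedom. Groups weigh equally in every contrast. Stage changes average the 4 combinations of population and diet. The age slope is the linear trend over 6 ages, from 3 to 24 days. Diet effects are organ pipe minus agria and population effects are Punta Prieta minus Las Bocas, averaged over the stages of a phase. Interactions are the diet effect in Punta Prieta minus that in Las Bocas. P-values were adjusted by Benjamini-Hochberg within each contrast. A transcript was called at an adjusted p under 0.05, and for a stage change also at an absolute log2 change of at least 1. Groups with 1 array take their error from the spread within the other groups.

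Gene lists and named genes had been fixed as patterns in gene product names. The annotation table given with the data pairs none of its genes with the array's transcript IDs (0 IDs matched), so those lists and their alternatives were not run. Under the rule set for that case, the text names the 2 called transcripts that rose and the 2 that fell most in each comparison, by ID. Diet, population and interaction effects at each of 13 single stages, 7 stage-profile groups and a maturation score were added after the data were examined. Of the single-stage effects, those of diet and population are described. For diet in adults, 3 and 6 days were followed up because they had the largest counts among the adult ages. The profile groups hold transcripts whose mean was at least 1 log2 unit higher in every stage of the group than in every other stage. For the egg and mature female group, these were eggs and females of 6 to 24 days against larvae and pupae. They were defined on these same arrays and are no independent evidence of a stage direction. They were tested with camera at a preset inter-gene correlation of 0.01, and again with the correlation estimated. Over the planned contrasts, the calls that hold with an estimated correlation are those of the adult group in the population effect in adults, in the population effect of adults minus larvae and in the interaction in adults.

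The maturation score of an array is its least-squares position between the 0-day mean (0) and the 10-day mean (1) of the 4 series, over 2467 transcripts that differ by at least 1 log2 unit between these means. Scores between first and second larval instars and between early and late pupae were made in the same way, with the series under study left out of the axis. Score differences between diets were tested by exact two-sided permutation of the diet labels within population.

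The steps were tested on simulated data with 200 changed transcripts among 14528. Normal noise was drawn independently for each transcript and array, with the transcript's SD within groups pooled over all stages. The simulation held no correlation between transcripts, no misplaced arrays and no larger spread in larvae or pupae. Its shares may therefore not carry over to the real data, above all in larvae and pupae. With a simulated change of 0.5 on the log2 scale, 68% of changed transcripts were recovered for the diet effect in larvae, 88% for the diet effect in adults, 27% for the population effect in eggs and 50% for the diet effect in pupae. With a change of 1 these shares were 98%, 100%, 90% and 89%. Of the calls, 14 of 180, 8 of 196, 6 of 123 and 4 of 143 were transcripts that had not been changed.

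Alternatives were a repeated quantile normalization, centring on array medians, leaving out the dimmest 25% of transcripts, array weights, a trended robust variance prior, a replicate block, a spread taken only from the stages compared, additive models, leaving out replicate numbers, single arrays, ages or stages with single-array groups. After the data were examined, leaving out 13 arrays that correlated better with another stage, by over 0.05, and array spread as a covariate were added. Regroupings of the samples numbered 100 for each comparison. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.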

Results

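Gene expression was followed through the life cycle of 2 wild-type populations of Drosophila mojavensis, from Las Bocas on the Sonoran mainland and from Punta Prieta in Baja California. Both were reared on laboratory media made from agria or from organ pipe cactus. The 172 arrays comprised 82 of Las Bocas and 90 of Punta Prieta, 97 on agria and 75 on organ pipe. There were 16 arrays of 6-hour eggs (E6), whose mothers had been raised on the given diet. Larvae contributed 45 arrays, with 14 of the first instar (L1), 16 of the second (L2) and 15 of the third (L3). Pupae contributed 25, with 14 early (EP) and 11 late (LP). Adult females contributed 86, with 18 at 0 days (0D), 15 at 3 days, 2 at 4 days, 14 at 6 days, 12 at 10 days, 10 at 14 days, 9 at 18 days and 6 at 24 days. Levels below are log2 signals, and group levels are means ± SD over arrays. A log2 change weighs the 4 combinations of population and diet equally, so it can differ from the difference of those means. Transcripts are named by the IDs in the data, which were not paired with gene names.

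Life stage separated the arrays far more than population or diet did. Stage took 76.3% of the variance over all transcripts, all 54 groups together took 85.4%, and 14.6% lay within groups. As effects shared by all stages, population added 0.621% to stage and diet added 0.2%. Most of what the groups added to stage thus lay in combinations of population, diet and stage. Of 14528 transcripts, 13196 had stage means that spanned at least 1 log2 unit, and the median span was 1.97. The highest stage mean lay in 6-hour eggs for 4002 transcripts, in first-instar larvae for 2312, in late pupae for 2070 and in 0-day females for 1902. Among the 170 arrays of the 13 stages compared, 105 correlated best with the mean of their own stage, taken without their own group. The means of other stages kept the array's own population and diet, so the comparison leans towards other stages. For 13 arrays, 10 of them larval, another stage's mean correlated better by over 0.05.

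**Figure D1:**
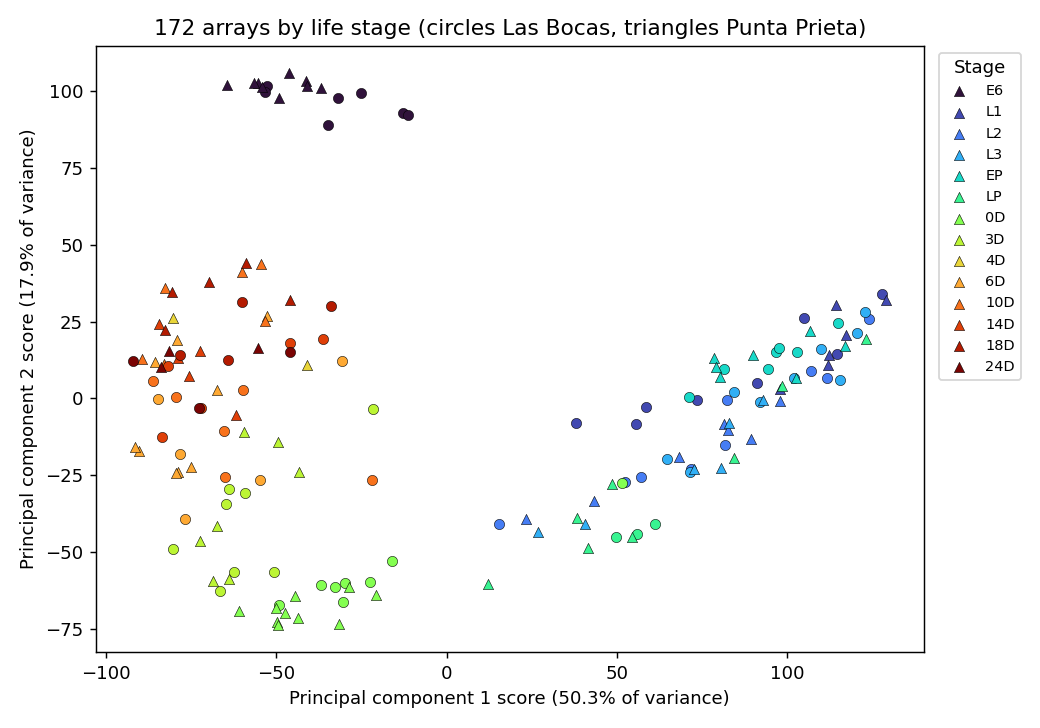
Scores of the 172 arrays on the first 2 principal components of the log2 signals, in arbitrary units, coloured by stage, with circles for Las Bocas and triangles for Punta Prieta. Component 1 (50.3% of the variance) sets larvae and pupae apart from eggs and adults, component 2 (17.9%) sets eggs apart from 0-day females, and 1 array labelled 0D lies among the larvae and pupae.

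The passage from egg to first-instar larva changed more transcripts than any other consecutive pair of stages, with 8456 called, 4344 higher and 4112 lower in larvae. FBtr0165068 rose from 9.03 ± 0.40 (SD, n = 16) in eggs to 14.57 ± 0.93 (n = 14), a log2 change of 5.38 (SE 0.22, adjusted p = 1.55e-47). FBtr0167405 rose by 5.17 (SE 0.16). FBtr0168096 fell by 4.78 on the log2 scale (SE 0.20), from 14.58 ± 0.22 to 9.80 ± 0.52, and FBtr0172232 fell by 4.56. A group of 121 egg transcripts averaged 12.39 in eggs and 10.35 in first-instar larvae. Centring on array medians shifted this comparison by -0.20 over all transcripts and turned the balance to 3671 higher and 4766 lower, with 3736 and 3824 after a repeated quantile normalization. With array spread as a covariate 5330 were called.

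Between the first and second larval instars 683 transcripts changed, 598 of them higher in the second. FBtr0171629 rose from 10.88 ± 0.29 (n = 14) to 14.23 ± 1.16 (n = 16), by 3.45 (SE 0.21, adjusted p = 1.96e-28), and FBtr0171630 rose by 3.38. FBtr0173238 fell by 2.52 on the log2 scale (SE 0.17) and FBtr0165117 fell by 1.75. From the second to the third instar 46 changed, 13 higher and 33 lower, led by FBtr0165510 with a rise of 3.01 (SE 0.37) and FBtr0168297 with a rise of 2.48. FBtr0172226 fell by 1.96 and FBtr0174331 fell by 1.63. The 90 larval transcripts averaged 13.23, 13.89 and 13.60 over the 3 instars and 10.00 in eggs. Without the 13 arrays that correlated better with another stage, 1363 and 118 transcripts were called in these 2 steps, and with the spread taken from second- and third-instar arrays alone 3 were called in the later step. Without replicate number 2 in any group the balance in the later step turned to 16 higher and 8 lower. Without replicate 1 of Las Bocas second-instar larvae on agria, or replicate 2 of Punta Prieta second-instar larvae on organ pipe, 29 were called in the later step.

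Pupariation came with 1532 changes, 818 higher and 714 lower in early pupae than in third-instar larvae, a balance that turned without replicate number 3 in any group (742 and 772) and without the dimmest 25% of transcripts (661 and 664). FBtr0165685 rose from 9.80 ± 0.37 (n = 15) to 15.43 ± 0.24 (n = 14), by 5.54 (SE 0.22, adjusted p = 5.75e-48), and FBtr0164349 rose by 5.27. FBtr0171495 fell by 6.11 on the log2 scale (SE 0.25), from 15.00 ± 0.79 to 8.92 ± 0.20, and FBtr0170671 fell by 5.19. From early to late pupae 3114 changed, 1345 higher and 1769 lower, a balance that turned after a repeated quantile normalization (1853 and 1822) and after centring on array medians (1586 and 1483). FBtr0171518 rose by 4.33 (SE 0.15) and FBtr0164156 by 4.16, while FBtr0163274 fell by 5.10 (SE 0.23) and FBtr0162411 fell by 5.02. The 84 early pupal transcripts averaged 13.77 in early and 11.23 in late pupae, and the 177 late pupal transcripts averaged 10.36 and 11.92.

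Eclosion changed 4481 transcripts, 2333 higher and 2148 lower in 0-day females than in late pupae. The groups give no sex before the adult stage. A difference in sex therefore cannot be told apart from stage in this step or in the profile groups. FBtr0171622 rose from 9.79 ± 0.48 (n = 11) to 14.31 ± 0.27 (n = 18), by 4.51 (SE 0.14, adjusted p = 4.94e-57), and FBtr0171207 rose by 4.08. FBtr0175038 fell by 4.82 on the log2 scale (SE 0.28) and FBtr0169045 fell by 4.74. The 75 adult transcripts averaged 11.01 in late pupae and 13.40 in 0-day females. The adult group stayed between 13.25 and 13.99 at later ages. The balance turned to 2044 higher and 2204 lower after a repeated quantile normalization and to 1946 and 2415 after centring on array medians. With array spread as a covariate 2431 transcripts were called at eclosion.

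**Figure D2:**
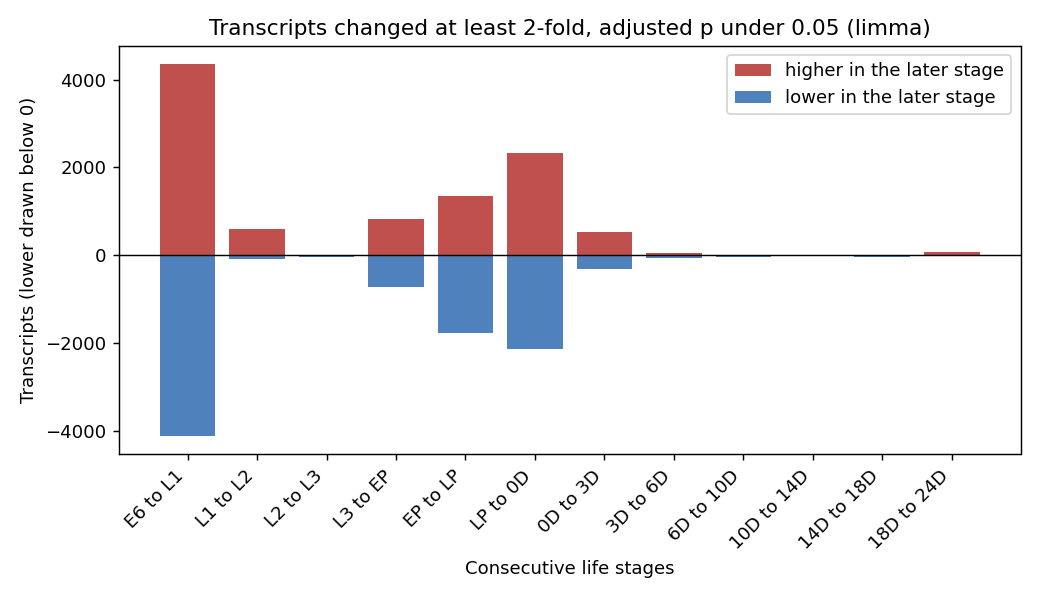
Number of transcripts that changed at least 2-fold at an adjusted p under 0.05 between consecutive stages, with rises above 0 and falls below 0. The tallest bars are those from egg to first-instar larva (4344 and 4112), and no bar is seen from 10 to 14 days (0 transcripts).

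During the first days of adult life, 832 transcripts changed between 0 and 3 days, 523 higher and 309 lower. FBtr0174527 rose from 8.17 ± 0.37 (n = 18) to 13.88 ± 0.37 (n = 15), by 5.71 (SE 0.14, adjusted p = 3.31e-68), and FBtr0168629 rose by 4.95. FBtr0167608 fell by 4.02 on the log2 scale (SE 0.19) and FBtr0163375 fell by 3.50. From 3 to 6 days 105 changed, 41 higher and 64 lower: FBtr0163649 rose by 2.60 (SE 0.38), FBtr0167326 rose by 2.57 (SE 0.20), FBtr0165237 fell by 3.43 and FBtr0168724 fell by 3.34. The 54 newly eclosed adult transcripts averaged 13.18 at 0 days, 11.52 at 3 days and 10.99 at 6 days. The 1128 egg and mature female transcripts averaged 11.47, 12.03 and 12.39 at these ages, against 12.85 in eggs and 10.61 in late pupae.

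Later steps in adult life involved few transcripts. From 6 to 10 days 39 changed, of which only FBtr0165468 rose, by 1.03 (SE 0.27), while FBtr0169215 fell by 1.84 (SE 0.22) and FBtr0164103 fell by 1.66. From 10 to 14 days limma called 0 transcripts, with 247 at an unadjusted p under 0.05 and 0 with array weights. From 14 to 18 days 49 fell, led by FBtr0168259, which fell by 2.32 (SE 0.41, adjusted p = 0.000154), and FBtr0162061, which fell by 2.20. From 18 to 24 days 68 rose, led by FBtr0168259 with 2.21 (SE 0.48, adjusted p = 0.00521) and FBtr0165335 with 1.99. From 18 to 24 days 26 were called after a repeated quantile normalization, 35 after centring on array medians and 2 without replicate number 2 in any group. These last 2 steps share the same 9 arrays of 18 days, and organ pipe had 1 array per population at both 18 and 24 days. Without replicate 2 of 24-day Punta Prieta females on agria 28 were called from 18 to 24 days, without replicate 2 of 24-day Las Bocas females on agria 34, and without replicate 3 of 18-day Las Bocas females on agria 44. From 6 to 10 days, 21 and 65 were called without replicate 2 and without replicate 1 of 10-day Punta Prieta females on organ pipe.

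Across 3 to 24 days, 5499 transcripts had a linear slope with age, 2962 upward and 2537 downward, and 5312 of these (96.6%) had the same sign in all 4 series, against 35.5% of the transcripts without a called slope. As the slope is the mean of the 4 series, the call itself favours a shared sign. Of the 5499, 215 rose and 334 fell by at least 1 log2 unit over the 21 days by their fitted slopes. These changes are the slope times 21 days, not the observed difference between 3 and 24 days. By its slope FBtr0167326 rose by 2.77 (0.132 per day, SE 0.0111, adjusted p = 1.77e-19), and FBtr0161868 rose by 1.65. The rise of FBtr0167326 was not even, as its step from 3 to 6 days alone was 2.57. By their slopes FBtr0161315 fell by 3.98 (adjusted p = 2.07e-30) and FBtr0167250 fell by 3.97. Among the 1128 egg and mature female transcripts 751 had an upward and 2 a downward slope, and among the 54 newly eclosed adult transcripts 42 had a downward slope. Neither group's call held with an estimated correlation (adjusted p = 0.188 and 0.0589), and both were defined on these arrays. Without the 3-day arrays, 405 transcripts had a slope, 160 upward and 245 downward, and the slope of FBtr0161868 no longer passed (0.0349 per day, adjusted p = 0.096).

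**Figure D3:**
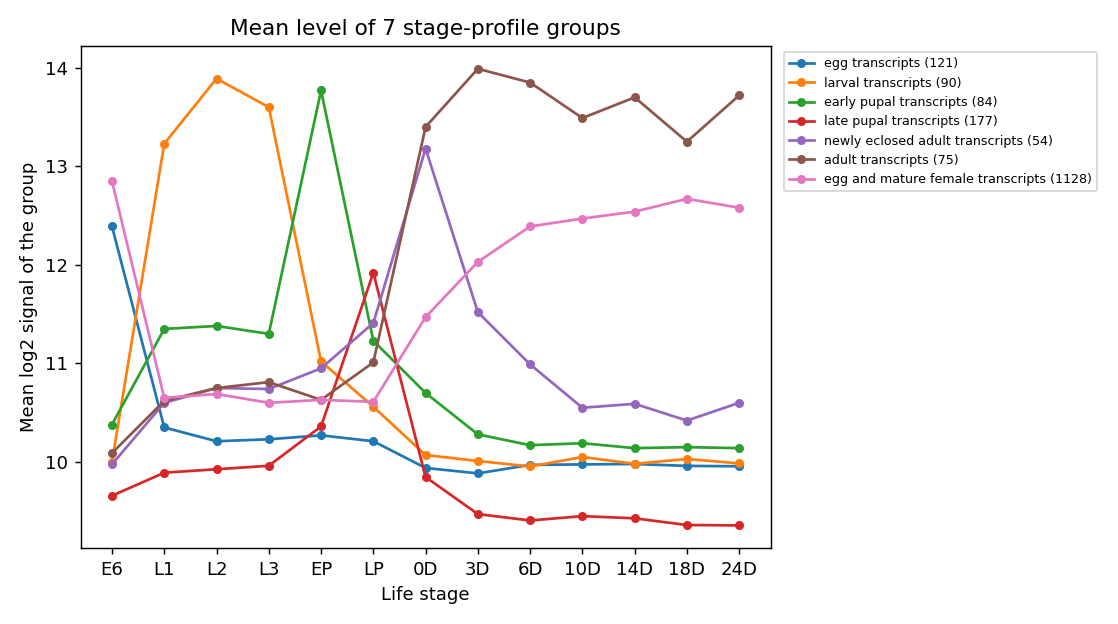
Mean log2 signal of 7 stage-profile groups at 13 stages, each point the mean of all members over the 4 series, with the number of members in the legend. The egg and mature female group falls from 12.85 in eggs to 10.65 in first-instar larvae and stands at 12.39 in 6-day females, and the newly eclosed adult group peaks at 13.18 at 0 days.

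The design sets agria against organ pipe medium in each phase. In larvae 688 transcripts differed by diet, 124 higher and 564 lower on organ pipe. FBtr0162264 was higher on organ pipe by 1.40 (SE 0.23, adjusted p = 4.11e-05), with 11.67 ± 1.76 (n = 18) against 10.64 ± 0.87 (n = 27), and FBtr0175522 was higher by 1.40 (SE 0.21). FBtr0172226 was lower (log2 change -1.29, SE 0.29), as was FBtr0164164 (-1.09, SE 0.17). Of the 90 larval transcripts 17 were lower and none higher, with a median of -0.30 (camera adjusted p = 6.6e-16, and adjusted p = 0.438 with an estimated correlation). At single instars the counts were 2195 in the first, 85 in the second and 979 in the last, which includes 1 group with a single array, and the first includes Las Bocas arrays on agria that lie nearer the second instar. After a repeated quantile normalization 307 were higher and 683 lower, and 423 differed without the 13 arrays nearer another stage. With only stages that have at least 2 arrays in each group, 11 were higher and 2 lower, so the balance turned. With the spread of larval arrays alone or in an additive model 0 differed, 88 did with array spread as a covariate, and 24 of 44 single arrays moved the count by over 1.5 times, from 66 without replicate 2 of Punta Prieta first-instar larvae on organ pipe to 1996 without replicate 1 of Las Bocas third-instar larvae on organ pipe.

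In adult females 267 transcripts differed by diet, 234 higher and 33 lower on organ pipe. FBtr0174650 was higher by 0.67 (SE 0.15, adjusted p = 0.00528), with 13.04 ± 0.70 (n = 35) against 12.27 ± 0.78 (n = 49), and FBtr0161265 was higher by 0.62 (SE 0.16). FBtr0163649 was lower (log2 change -0.86, SE 0.25), as was FBtr0168259 (-0.86, SE 0.20). Of the 54 newly eclosed adult transcripts 7 were higher and none lower (camera adjusted p = 7.31e-12, and adjusted p = 0.188 with an estimated correlation). Counts of 92 after a repeated quantile normalization and 2412 in an additive model show how far the number moves with the model. Without replicate 2 of 24-day Las Bocas females on agria 152 differed, and without replicate 1 of 3-day Punta Prieta females on agria 412.

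Among single adult ages, compared after the data had been examined, 3 and 6 days had the highest counts by diet. Whether the effect differs between ages was not tested. At 3 days 1716 transcripts differed, 1050 higher and 666 lower on organ pipe, and at 6 days 502, 370 higher and 132 lower. At 0, 10, 18 and 24 days the counts were 1, 26, 1 and 1, and at 14 days limma called 0, with 318 at an unadjusted p under 0.05. At 10 days 2163 had an unadjusted p under 0.05. The SD of the log2 changes over transcripts was 0.335 at 10 days and 0.349 at 3 days. Organ pipe had 2 arrays per population at 10 and 14 days and 1 at 18 and 24 days. Low counts at these ages therefore do not show that the effect was absent. At 3 days FBtr0162061 had 10.84 ± 1.98 (n = 8) on organ pipe and 14.00 ± 1.19 (n = 7) on agria, a log2 change of -3.10 (SE 0.41, adjusted p = 1.27e-07), and FBtr0168259 had a change of -2.82 (SE 0.42). FBtr0166696 was higher by 1.30 (SE 0.19) and FBtr0170953 by 1.24 (SE 0.17). Of the 1128 egg and mature female transcripts 241 were lower and 2 higher on organ pipe at 3 days. Among the 54 newly eclosed adult transcripts 22 were higher and none lower at 3 days, and 16 were higher and none lower at 6 days. With an estimated correlation and adjustment over all 7 adult ages, none of these calls held (adjusted p = 0.543, 0.0782 and 0.139). After a repeated quantile normalization 1031 differed at 3 days, 560 higher and 471 lower, and 250 at 6 days, 198 higher and 52 lower. After centring on array medians the 6-day counts were 336 and 314, and with the spread of 6-day arrays alone 19 were higher and none lower. Without replicate number 3 in any group the 3-day count was 188 and without replicate number 2 it was 242, and the balance turned in both (69 higher and 119 lower, 102 higher and 140 lower). With array weights it was 3578 higher and 3657 lower, and without replicate number 2 the 6-day count was 19.

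On a score that is 0 at the 0-day mean and 1 at the 10-day mean, 3-day females on organ pipe lay lower than those on agria. Las Bocas females scored 0.399 ± 0.089 (n = 4) on organ pipe and 0.708 ± 0.076 (n = 4) on agria, and Punta Prieta females 0.499 ± 0.16 (n = 4) and 0.715 ± 0.17 (n = 3). The mean difference was -0.263 (exact permutation p = 0.0049, adjusted p = 0.0175 over 4 ages), and 8 of 8 organ pipe arrays lay below the agria mean of their population. At 6 days the difference was -0.217 (exact permutation p = 0.00873, adjusted p = 0.0175), with 6 of 6 organ pipe arrays below that mean. At 0 days it was -0.0054 (exact permutation p = 0.877) and at 10 days -0.0465 (exact permutation p = 0.458). Neither of these passed the test.

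**Figure D4:**
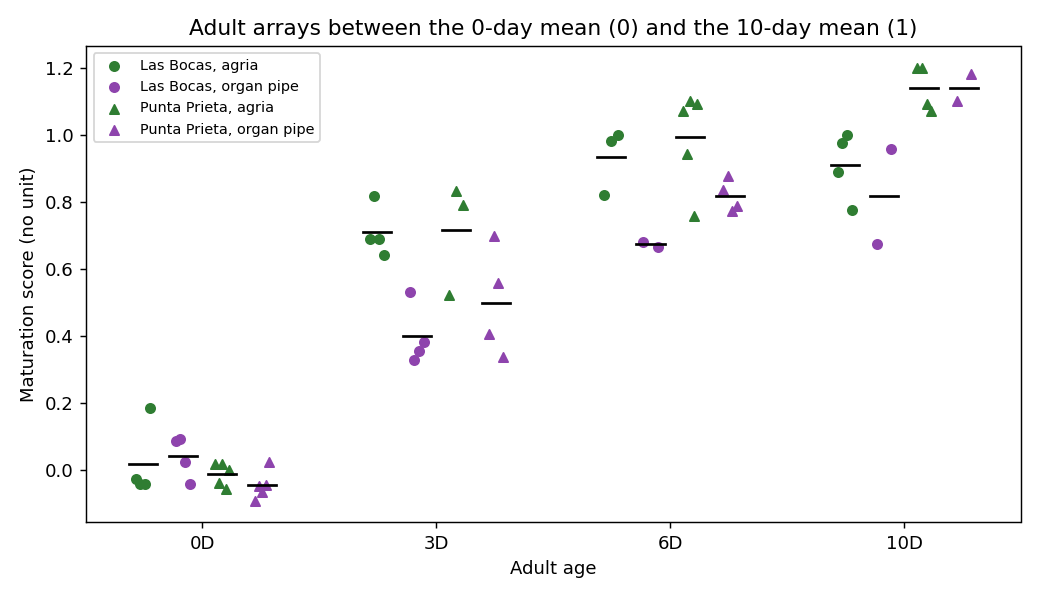
Maturation score (no unit) of each adult array at 0, 3, 6 and 10 days, with green for agria, purple for organ pipe, circles for Las Bocas, triangles for Punta Prieta and bars for group means. At 3 days the organ pipe arrays lie between 0.33 and 0.70 and the agria arrays between 0.52 and 0.83.

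Diet was also compared in eggs and pupae. In eggs, which differ in the diet of their mothers, limma called 0 transcripts, with 152 at an unadjusted p under 0.05 and 3 with array weights. In pupae 61 differed, 34 higher and 27 lower on organ pipe, or 47 and 18 after centring on array medians and 81 and 49 after a repeated quantile normalization. The balance turned with array spread as a covariate (128 and 133) and without replicate number 3 in any group (3 and 9). FBtr0168724 was higher by 1.45 (SE 0.31, adjusted p = 0.00672) and FBtr0163131 by 1.21 (SE 0.30), while FBtr0171630 and FBtr0163418 were lower (log2 changes -1.04 and -1.02). With the spread of pupal arrays alone 0 differed, as in an additive model. In early pupae alone, where each group has at least 2 arrays, 73 were higher and 200 lower, so the balance turned, and in late pupae alone 1368 differed. The late pupal count includes a group with a single array, Las Bocas on organ pipe, and 2 arrays nearer earlier stages. Without these 2 arrays 15 differed in pupae. Among single arrays of pupae 8 of 24 moved the count by over 1.5 times, from 30 without replicate 3 of late Punta Prieta pupae on agria to 747 without replicate 1 of late Las Bocas pupae on agria.

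**Figure D5:**
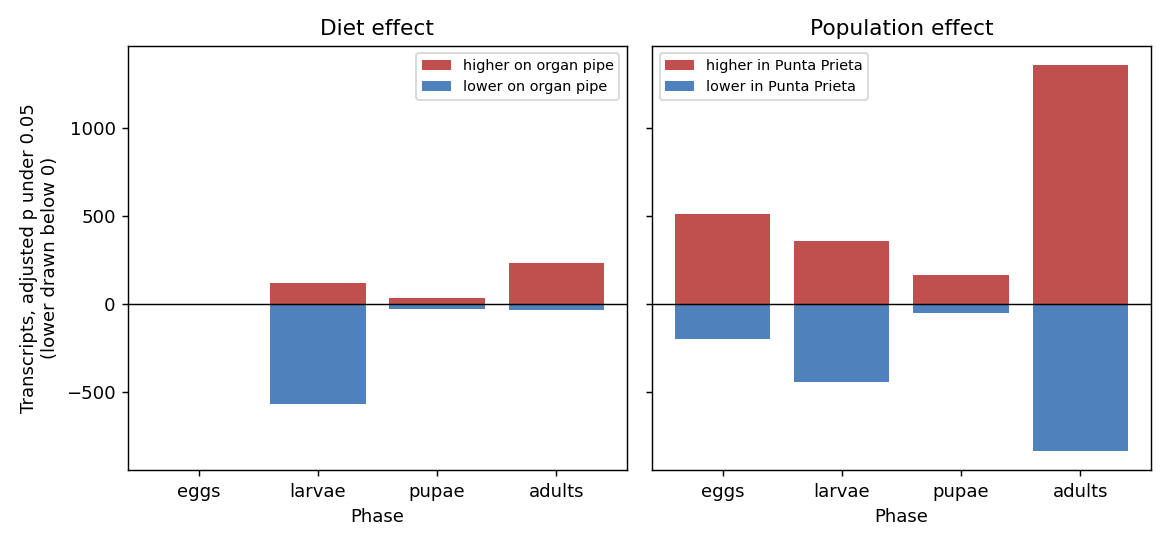
Number of transcripts that differed between diets (left) and populations (right) in 4 phases at an adjusted p under 0.05, with higher on organ pipe or in Punta Prieta above 0 and lower below 0. The adult population bars (1358 and 832) are the tallest, and eggs have no diet bar (0 transcripts).

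The populations were compared in each phase. In adult females 2190 transcripts differed, 1358 higher and 832 lower in Punta Prieta. FBtr0165463 was higher by 2.13 (SE 0.14, adjusted p = 1.48e-25), with 12.23 ± 0.58 (n = 45) against 10.11 ± 0.71 (n = 39), and FBtr0167831 was higher by 2.00 (SE 0.13). FBtr0167365 was lower, with 10.80 ± 0.98 against 13.65 ± 0.88 (log2 change -2.85, SE 0.14, adjusted p = 3.52e-37), as was FBtr0175016 (-1.94, SE 0.13). Of the 75 adult transcripts 32 were lower and 1 higher in Punta Prieta, and that call held (adjusted p = 0.049 with an estimated correlation). Among the 1128 egg and mature female transcripts 426 were higher and none lower (adjusted p = 0.188 with an estimated correlation). At single ages, 3055 differed at 10 days, against 360, 52, 22, 14 and 43 at 0, 3, 6, 14 and 18 days, and limma called 0 at 24 days, with 141 at an unadjusted p under 0.05. Whether the population effect differs between ages was not tested. After a repeated quantile normalization 1452 differed, and without replicate 1 of 10-day Las Bocas females on organ pipe 1453.

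In eggs 711 transcripts differed between populations, 513 higher and 198 lower in Punta Prieta. FBtr0166843 had 11.04 ± 0.37 (n = 9) in Punta Prieta and 8.45 ± 0.34 (n = 7) in Las Bocas, a log2 change of 2.61 (SE 0.19, adjusted p = 6.21e-22), and FBtr0164933 was higher by 1.77 (SE 0.21). FBtr0171396 was lower (log2 change -1.75, SE 0.22), as was FBtr0173167 (-1.45, SE 0.23). Of the 121 egg transcripts 23 were lower and 8 higher (adjusted p = 0.618 with an estimated correlation). After a repeated quantile normalization 235 were higher and 124 lower. Without replicate number 3 in any group 19 were higher and 48 lower, so the balance turned. Among single arrays of eggs 6 of 16 moved the count by over 1.5 times, from 301 without replicate 3 of Las Bocas eggs on agria to 1237 without replicate 1 of the same group.

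In larvae 797 transcripts differed between populations, 359 higher and 438 lower in Punta Prieta. FBtr0164933 had 9.63 ± 0.32 (n = 19) in Punta Prieta and 7.59 ± 0.07 (n = 26) in Las Bocas, a log2 change of 2.10 (SE 0.14, adjusted p = 7.56e-27). The Las Bocas level lies near the lowest value in the data (7.25) and is not shown to be above background, so the size of this change, and of that in eggs, is uncertain. FBtr0167648 was higher by 1.96 (SE 0.21). FBtr0172631 was lower (log2 change -1.60, SE 0.22), as was FBtr0169031 (-1.23, SE 0.20). The balance in larvae turned with the spread of larval arrays alone (208 higher and 167 lower), in an additive model (294 and 242) and without replicate number 2 in any group (154 and 100). With only stages that have at least 2 arrays in each group it was 420 and 1001. At single instars the counts were 3671, 130 and 391 from the first to the last. The first includes Las Bocas arrays on agria that lie nearer the second instar, and the last includes a group with a single array. In pupae 215 differed, 166 higher and 49 lower, or 278 and 153 after a repeated quantile normalization. FBtr0167831 was higher by 1.47 (SE 0.23) and FBtr0161951 by 1.45 (SE 0.19), and FBtr0172631 and FBtr0173223 were lower (log2 changes -1.10 and -1.07). With the spread of pupal arrays alone 0 differed in pupae and in an additive model 2, and at single stages 69 differed in early and 375 in late pupae. The late pupal count includes a group with a single array, Las Bocas on organ pipe. Without the 2 late pupal arrays nearer earlier stages 73 differed in pupae, and single arrays moved that count from 18 to 1832, both among the 2 late Las Bocas arrays on agria (replicates 1 and 2).

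The diet effect was compared between populations by the interaction. In pupae 334 transcripts had a diet effect that differed between populations, 198 higher and 136 lower in Punta Prieta. FBtr0165497 had an interaction of 3.35 (SE 0.61, adjusted p = 0.000481), which turned to -0.60 in early pupae alone (adjusted p = 0.992). FBtr0169215 had 2.94 (SE 0.47), while FBtr0161926 had -2.26 and FBtr0164111 had -1.69. In larvae 30 did, 2 higher and 28 lower, among them FBtr0161901 with 1.56 (SE 0.38), FBtr0169724 with 0.92, FBtr0162415 with -2.25 and FBtr0170864 with -2.10. In eggs and in adults limma called 0, with 839 and 631 at an unadjusted p under 0.05 and 1026 and 108 with array weights. For the 75 adult transcripts, none of which passed singly, the median interaction in adults was -0.30, a shift that held with an estimated correlation (adjusted p = 0.0124). That test was not repeated without replicate 4 of 0-day Las Bocas females on agria. This array correlated better with the second-instar mean (0.881) than with its own stage (0.821), so its part in the shift is not known. Centring on array medians shifted the interaction in eggs by 0.10 over all transcripts, and without replicate 1 of Las Bocas eggs on agria 19 were called. With the spread of the phase's arrays alone 0 were called in pupae and 0 in larvae, and 0 in larvae with only stages that have at least 2 arrays in each group. Without the dimmest 25% of transcripts the balance in pupae turned to 102 higher and 118 lower, and in early pupae alone to 13 and 22. Without the 2 late pupal arrays nearer earlier stages, 51 interactions were called in pupae, and 15 of 24 single arrays moved that count by over 1.5 times, from 94 without replicate 3 to 1769 without replicate 4 of late Punta Prieta pupae on agria. In larvae 12 and 72 were called without replicate 1 of Punta Prieta first-instar larvae on organ pipe and without replicate 1 of Las Bocas first-instar larvae on agria.

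Diet and population effects were also compared between adults and larvae. The diet effect differed for 843 transcripts, 583 higher and 260 lower in adults, with FBtr0161265 at 1.57 (SE 0.26, adjusted p = 0.000338), FBtr0162989 at 1.42, FBtr0162264 at -1.46 and FBtr0173060 at -1.45. The population effect differed for 1110, 643 higher and 467 lower in adults. FBtr0167365 led the falls (log2 difference -2.02, SE 0.23, adjusted p = 3.33e-10), followed by FBtr0163329 at -1.48, and FBtr0175546 at 1.02 and FBtr0170903 at 0.94 led the rises. Of the 75 adult transcripts 23 had a lower population effect in adults and none a higher one (adjusted p = 0.049 with an estimated correlation). The balance of the population difference turned with array spread as a covariate (746 higher and 847 lower) and without replicate number 2 (77 and 102) or 3 (219 and 222) in any group. That of the diet difference turned with array weights (2350 and 2387). For the diet difference, 513 were called without the 13 arrays nearer another stage, 75 with array spread as a covariate, 260 without replicate 2 of Punta Prieta first-instar larvae on organ pipe and 2199 without replicate 1 of Las Bocas third-instar larvae on organ pipe.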

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

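The tests of explanations in this part, the regroupings of samples and the leaving out of 2 late pupal arrays were chosen after the results had been seen, while the tests of differences between phases and populations were planned. In 56 tests of the array spread and of the correlation with other arrays of the stage, within groups of 4 or 5, 7 values, on 6 arrays, stood apart from the others of their group, and chance gives about 1 in 20.

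Replicate 4 of 0-day Las Bocas females on agria stood apart in both measures, with an SD of 1.48 against 1.63 to 1.67 and a correlation of 0.821 against 0.968 to 0.988. Replicate 4 of early Las Bocas pupae on agria had an SD of 1.42 against 1.45 to 1.46. Replicate 2 of 3-day Las Bocas females on agria had an SD of 1.59 against 1.68 to 1.70. Replicate 5 of 0-day Punta Prieta females on organ pipe had an SD of 1.63 against 1.70 to 1.72. Replicate 4 of Las Bocas first-instar larvae on organ pipe had a correlation of 0.889 against 0.962 to 0.972, and replicate 4 of 6-day Punta Prieta females on organ pipe had 0.974 against 0.977.

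By tests of the difference itself, the diet effect differed between populations for 334 transcripts in pupae and 30 in larvae, and between adults and larvae for 843. The population effect differed between adults and larvae for 1110. Among 100 regroupings, the pupal count was reached in 29 and the larval count in 6, so chance cannot be excluded for either, with 4385 and 1378 in the highest of the others. Each taken by itself, without adjustment over comparisons, chance can be excluded for the 843 (1 of 100, highest other 584) and for the 1110 (2 of 100, highest other 2428).

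Las Bocas arrays on agria of the first and second instars lay towards each other's stage. On an axis from first to second instar made from the other 3 series, 4 of 4 first-instar arrays scored above 0.5 (0.547 to 0.881) and 3 of 5 second-instar arrays below 0.5 (-0.187, 0.272 and 0.399). With all arrays given the same distribution the counts were still 4 and 3, which argues against array spread. Exchanged labels between the instars may account for some of them, but the scores restate the pattern and do not decide. Of these 3, replicates 3 and 4 correlated best with the first-instar mean and replicate 5 (0.399) with the third-instar mean. That first-instar mean included the 4 first-instar arrays of this series, which are themselves in doubt. These correlations therefore do not decide on an exchange. Exchanged labels cannot be told apart from larvae near a moult or different developmental rates in this series, which were not tested and stay open.

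Replicates 2 and 3 of late Punta Prieta pupae on agria lay with early pupae. On an axis from early to late pupae made from the other 3 series, they scored 0.089 and 0.024, under the highest early pupal array at 0.13, and with the same distribution in all arrays the higher of them scored 0.077, which argues against array spread. Early pupae under a late pupal label could account for both, but the scores restate the pattern, and such labels cannot be told apart from slower development of pupae in this group, which was not tested. Replicates 1 and 4 of this group scored 0.644 and 0.792, below the lowest late pupal array of the other series at 0.867. Replicate 3 correlated best with the first-instar mean (0.902), as did 1 of the early pupal arrays (0.913). Without replicates 2 and 3 the interaction in pupae fell from 334 to 51 transcripts.

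Females on organ pipe at 3 days lay nearer newly eclosed females than those on agria did. The exact permutation p was 0.0049, with 8 of 8 organ pipe arrays below the agria mean of their population, and it was again 0.0049 with the same distribution in all arrays, which argues against array spread. No organ pipe array (0 of 8) lay within the range of the 0-day arrays, whose highest score was 0.18, which argues against newly eclosed females under a 3-day label. Slower maturation of females on organ pipe and a difference between the diets in the exact age at collection cannot be told apart, since the score restates the pattern and the labels give no ages finer than days. Neither population was tested alone, and the ranges of the 2 diets overlapped in Punta Prieta.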

How the results depend on the processing

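Direction and call were kept in 1362 of 1498 values of the named transcripts under other settings. In the same direction, 135 fell short of the threshold, and 50 of 87 pairs of transcript and comparison passed in every value counted. Of the fits without a single array, only those with the lowest and the highest log2 change of a transcript were counted. A call lost in another such fit is therefore not seen here. The 1 reversal was the interaction of FBtr0165497 in pupae, which was -0.60 when only stages with at least 2 arrays in each group were used, a setting that leaves early pupae alone. The cause of the other movements was not tested unless the setting itself removes samples. Counts for the steps at pupariation, early to late pupa, 0 to 3 days, 3 to 6 days and 10 to 14 days stayed within 1.5 times under every alternative, and the trended robust prior moved no count by more. Array spread as a covariate and the leaving out of 13 or of 2 arrays were chosen after the data were examined. The alternatives for gene lists were not run, as no transcript ID was paired with a gene name. Without scanner files, signal over background was not analysed here, so dim transcripts were judged by their mean alone.

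With array spread as a covariate, counts were 5330 from egg to first-instar larva, 452 and 30 in the next 2 larval steps and 2431 at eclosion. Diet effects were 88 in larvae and 261 in pupae, population effects 1382 and 662, the larval interaction 47 and the diet difference between adults and larvae 75. Without the 13 arrays nearer another stage, the first 2 larval steps gave 1363 and 118, diet effects 423 in larvae and 15 in pupae, the population effect in pupae 104, the pupal interaction 63 and the diet difference between adults and larvae 513. Without the 2 late pupal arrays, the pupal diet, population and interaction counts were 15, 73 and 51. Without the dimmest transcripts, the step between the last 2 larval instars gave 29 and the pupal interaction 220, with fewer transcripts tested.

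After a repeated quantile normalization, counts were 25 from 6 to 10 days, 32 from 14 to 18 days and 26 from 18 to 24 days. Diet effects were 130 in pupae and 92 in adults, population effects 359 in eggs, 431 in pupae and 1452 in adults, and the pupal interaction 535. Centring on array medians gave 35 from 18 to 24 days. Without the 3-day arrays the age slope was called for 405 transcripts.

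Array weights, whose estimation stopped before convergence, raised the diet counts to 3 in eggs, 3400 in larvae, 277 in pupae and 3283 in adults. They raised the population counts to 3468, 3004, 649 and 5778, the interactions to 1026, 647, 2558 and 108, and the differences between adults and larvae to 4737 for diet and 4053 for population. With the spread from the stages compared alone, the step between the last 2 larval instars gave 3, diet effects 0 in larvae, 0 in pupae and 796 in adults, and population effects 375, 0 and 4302. The interactions in larvae and pupae gave 0 and 0, and the diet difference between adults and larvae 1395. Additive models gave diet effects of 0 in larvae, 0 in pupae and 2412 in adults, and population effects of 1269 in eggs, 2 in pupae and 4396 in adults. With only stages that have at least 2 arrays in each group, diet effects were 13 in larvae, 273 in pupae and 835 in adults, population effects 1421 in larvae and 69 in pupae, interactions 0 in larvae and 35 in pupae, and the diet difference 257.

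Replicate numbers did not pair the arrays. Deviations of same-numbered arrays of different groups of a stage had a median correlation of 0.000536 over 194 pairs, 79 of them over 0.1, and 31 of 160 arrays correlated best with an array of their own number. With a replicate block, 1066 transcripts differed by diet in larvae and 139 by population in pupae, and no other count moved by over 1.5 times.

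Over the settings that left out a replicate number or a single array, counts ran from 24 to 66 between the last 2 larval instars, 7 to 68 from 6 to 10 days, 13 to 69 from 14 to 18 days and 2 to 143 from 18 to 24 days. Diet effects ran from 23 to 1996 in larvae, 12 to 2501 in pupae and 49 to 412 in adults. Population effects ran from 67 to 1237 in eggs, 254 to 1053 in larvae, 18 to 2103 in pupae and 897 to 2697 in adults. Interactions ran from 0 to 19 in eggs, 3 to 72 in larvae and 1 to 1769 in pupae. The differences between adults and larvae ran from 82 to 2199 for diet and 179 to 1448 for population. A group left with 1 array is assumed to vary like the other groups.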

Other observations

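The comparisons in this part, of population and diet effects across phases and of regrouped samples, were chosen after the results had been seen. Population effects in eggs and in adult females ran in the same direction. Of the 711 transcripts called in eggs and the 2190 called in adults, 319 were called in both and 314 of these had the same direction, against 59.3 with the same direction for independent lists. The correlation of the 2 effects across transcripts, which are not independent replicates, was 0.552, outside the range of 99 other regroupings of the population labels (-0.457 to 0.529). The population effect in adults on agria and that on organ pipe, from separate arrays, correlated at 0.65 (regroupings -0.516 to 0.519). Larvae and adults shared 170 calls, 137 of them in the same direction against 58.6 for independent lists, while their effects correlated at 0.147, which 36 of 100 regroupings matched in size. The pairs of phases were not tested against each other. The eggs and the adult females come from separate arrays, and the eggs were 6 hours old.

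A set of 7 transcripts differed between populations in the same direction in all 4 phases. The calls in pupae rest on the pooled spread: 0 transcripts passed in pupae with the spread of pupal arrays alone and 2 in an additive model, so at most 2 of the 7 pass in all 4 phases there. FBtr0164933, near the lowest level of the data in Las Bocas eggs and larvae, was higher in Punta Prieta by 1.77 in eggs, 2.10 in larvae, 1.25 in pupae and 1.60 in adults. FBtr0172631 was lower, with log2 changes of -1.31, -1.60, -1.10 and -0.94. FBtr0167653 was higher by 0.94, 1.89, 1.11 and 0.85. Whether sequence differences between the populations under the probes contribute was not tested, as no probe sequences were used here.

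Diet effects in larvae and adults had a correlation of -0.362 across transcripts, which 14 of 100 regroupings of the diet labels matched in size. The larval diet effects of Las Bocas and Punta Prieta correlated at 0.555, which 13 of 100 regroupings matched. Neither value stands outside the range that relabelled arrays give.

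The single 4-day arrays of Punta Prieta females entered no comparison. The agria array correlated best with the 14-day mean (0.978) and the organ pipe array with the 18-day mean (0.983).

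Each count of called transcripts was set against 100 regroupings, the real one included. A share under 5% was taken to exclude chance for that comparison by itself, with no adjustment over the comparisons. For stage changes and the age slope, labels were permuted within population and diet and the fit held only the arrays compared, so the real counts differ from those above. Chance can be excluded from egg to first instar (real 8456, highest other 2397), from first to second instar (682, 663), between the last 2 larval instars (3, 0), at pupariation (1530, 0), from early to late pupae (3109, 2295) and at eclosion (4483, 0), each reached by 1 of 100. The same holds from 0 to 3 days (832, 0), 3 to 6 days (102, 19) and 6 to 10 days (38, 11). It also holds from 14 to 18 days (49, 4) and for the age slope (7375, 463). Each of these counts was reached by 1 of 100. From 18 to 24 days 3 of 100 reached the real count (70, highest other 77), so the exclusion is weak there. From 10 to 14 days the real count was 0 and the highest other 1, so all 100 reached it. For the last 2 larval instars the exclusion rests on 3 calls and on the draw: an earlier, smaller set of regroupings, in which repeats had not been removed, held 1 with more calls than the real grouping. Both sets stay under 5%, but the exclusion is weak.

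For diet in larvae 4 of 100 reached the real count (688, highest other 2526), so the exclusion of chance is weak. For diet in adults chance can be excluded with 2 of 100 (267, 2163). At 3 days (1716, 830) and 6 days (502, 34) 1 of 100 reached the real count, but these ages had been picked by their counts. For the largest count over 7 adult ages, which is that at 3 days, chance can be excluded with 1 of 100 (1716, 830), and for 6 days this was not tested. It cannot be excluded in pupae with 44 of 100 (61, highest other 5413), nor in eggs, where the real count was 0 and the highest other 82 (100 of 100). For population, chance can be excluded in eggs with 2 of 100 (711, 745) and in adults with 1 (2190, 14), and not in pupae with 45 (215, 6544). In larvae 4 of 100 reached the real population count (797, 5282), so the exclusion is weak there too. The interactions in eggs (0, highest other 98) and adults (0, 10) were reached by all 100. Regroupings that called several times the real count, in larvae, in pupae and for diet in adults, may reflect a structure among the samples, such as misplaced stage labels, or a pooled spread too small for these arrays. No regrouping was run without the 13 arrays nearer another stage or with the spread of a phase alone, so neither was tested by regrouping. With the spread of a phase alone, the real diet counts were 0 in larvae, 0 in pupae and 796 in adults, against 688, 61 and 267. Those larval and pupal counts go with a pooled spread too small for these phases, though the fit also held fewer arrays. The adult count argues against it for adults.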
